A study of Homo sapiens with 4 samples.

How the data were processed

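DREAM (digital restriction enzyme analysis of methylation) reads the methylation state of a CCCGGG site from the end that 2 enzymes leave on it. Per the labels' protocols, genomic DNA was first cut with SmaI, which is blocked by methylation and leaves blunt ends, and then with XmaI, which cuts the methylated sites left over. The fragments were size selected, amplified by PCR and sequenced in pairs on an Illumina Genome Analyzer II. The DNA came from HEK293T cells, an established human embryonic kidney line carrying the SV40 large T antigen. The cells were transfected with 1 of 4 TET1 expression plasmids that also carried a GFP reporter, and GFP-positive cells were sorted on day 3 (mTET1-CD and TET1-CD) or day 7 (mTET1-FL and TET1-FL). The series holds 1 library per plasmid.

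The authors deposited 1 table per library with the same 378726 CCCGGG sites. Each row holds a site's position, the count of reads with a methylated end, the count of reads with an unmethylated end and, per the file headers, a methylation value. The deposited counts are raw whole numbers with no normalization. The deposited methylation value is a percent, and it equalled the percentage of methylated reads at each covered site to within 5.00e-09. The genome build is hg18, per the submitters' processing notes. The aligner, the read filters and the way reads were assigned to sites are not given in the sources used here. PCR duplicates cannot be told from separate molecules in such counts, so the intervals cover counting error only.

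In the deposited TET1-CD table none of the methylated or unmethylated counts was odd (0 of 95131 non-zero values), whereas 40914 methylated counts of mTET1-CD were odd. The TET1-CD counts were therefore divided by 2 before any filter or test. This left the percentages as they were and lowered the depth from 17158344 to 8579172 reads. The planned design had assumed 1 read per count, and the unhalved counts were kept as an alternative chosen after seeing the data.

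Sites with at least 20 reads in all 4 libraries were used, which left 30593 sites, or 8.08% of those listed. Among these, 73 lie on sequences of the assembly that are unplaced within a chromosome or are alternative haplotypes. The median depth per site was 292 reads in mTET1-CD, 197 in TET1-CD, 855 in mTET1-FL and 703 in TET1-FL. For each site the change was the methylation level of the unmutated construct's library minus that of the m construct's library on the same day, in percentage points. Means over sites carry a 95% counting interval. Medians over sites carry a 95% interval from order statistics. It is an interval for the median that treats sites as independent, and it does not show how widely single sites vary. Sites are not replicates, and neighbouring sites are not independent. Levels at single sites carry Wilson 95% intervals, and a count of 0 is given with the share that 3 reads would make.

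Each site was tested with a two-sided Fisher's exact test on its reads with Benjamini-Hochberg adjustment over the 30593 sites. A site was called lowered or raised at an adjusted p below 0.05 and a change of at least 20 points. With 1 library per group this test compares 2 libraries and not 2 conditions. The same test between mTET1-FL and mTET1-CD served as a yardstick for libraries without an unmutated construct, although construct and day differ between them. Depth per site on the log2 scale correlated more closely within the CD pair (0.896) and the FL pair (0.969) than across them (0.506 to 0.744), and each contrast was made within a pair. The difference between the 2 changes (TET1-CD minus TET1-FL) was tested per site with a z test after adding 1 methylated and 1 unmethylated read per library. Sites were sorted into baseline classes by the m library of the other contrast, so that noise in the library used for a change did not choose the sites.

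On simulated reads with the real depths, the Fisher test called 41 of 50 sites with a fall of 25 points and 47 of 50 with a fall of 40 points in the TET1-CD comparison, and 42 of 50 and 49 of 50 in the TET1-FL comparison. At a fall of 10 points, below the size threshold, 0 of 50 sites were called in either comparison. Among 30393 unchanged sites there were 1 and 0 calls. The test of the difference called 176 of 200 sites with a fall of 40 points in TET1-CD alone and 4 of 30393 unchanged sites. The simulated reads carried binomial error only, whereas the variance between the real m libraries was 5.77 times the binomial one. These counts of false calls therefore cover the sampling of reads and not differences between libraries.

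The sites named in the text were chosen by a rule. Among called sites with at least 50 reads in all 4 libraries, it took the 10 largest falls and the 5 largest rises per contrast, and the 10 largest differences between the contrasts. It allowed at most 1 site per 100 kb window and broke ties by depth. The part of the rule that named promoter sites of listed genes was not applied, because sites were not assigned to genes. The tests per site, thresholds, classes, naming rule and most alternative settings were chosen before the data were examined. Added later were the halving, 2 further settings, the counts of sites that stayed at 90% or above, the matched comparison of neighbour classes (also on split reads of the m libraries), the breakdown of called sites by the other pair, and the comparisons by chromosome, by distance and at unmethylated sites. Sites are given by hg18 chromosome and position as deposited, and which base of the site a position marks is not given in the sources used here. Gene, exon and CpG island annotation of that build was not used here, so no site was assigned to a gene and 8 gene lists fixed beforehand were not tested. The spiked-in methylation standards were not analysed here. The alternatives were other read minimums, site sets, weightings, thinning, size thresholds, an inflated variance, and other class and window definitions. Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.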

Results

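DNA methylation was measured at single CCCGGG sites in HEK293T cells that overexpressed 1 of 4 TET1 constructs. TET1 is a dioxygenase that oxidises 5-methylcytosine. How the 2 enzymes cut sites that carry the oxidised forms was not examined here. A methylation level below is therefore the share of reads with a methylated end. In published use of these construct names, CD stands for the catalytic domain, FL for the full-length protein, and the prefix m for a form mutated in the catalytic site. The labels do not spell them out. The libraries held 13122070 reads for mTET1-CD, 8579172 for TET1-CD after halving its even-numbered counts, 35505013 for mTET1-FL and 33118276 for TET1-FL. Positions are in hg18, per the submitters' processing notes, and the gene annotation of the sites was not used here. There were no replicates, so a difference can be set only against the difference between the 2 m libraries.

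The 4 libraries were first compared over the 30593 sites read in all of them. With each site counted once, the mTET1-CD, mTET1-FL and TET1-FL libraries had nearly equal mean methylation, and TET1-CD stood below them. The mean over sites was 34.8% in mTET1-CD, 28.9% in TET1-CD, 34.7% in mTET1-FL and 34.5% in TET1-FL. The counting error of these means was at most 0.0163 points. Weighted by each library's own reads, the means were 29.3%, 23.3%, 37.6% and 39.8% in the same order. Sites below 10% made up close to the same share of each library, from 49.6% in mTET1-FL to 52.0% in TET1-CD. The upper end differed, since sites of at least 90% made up 15.3% of mTET1-CD, 14.0% of mTET1-FL and 13.6% of TET1-FL but 4.02% of TET1-CD. Sites from 30% to under 70% made up 19.95% of TET1-CD, against 13.5% of mTET1-CD, 14.3% of mTET1-FL and 14.6% of TET1-FL.

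**Figure D1:**
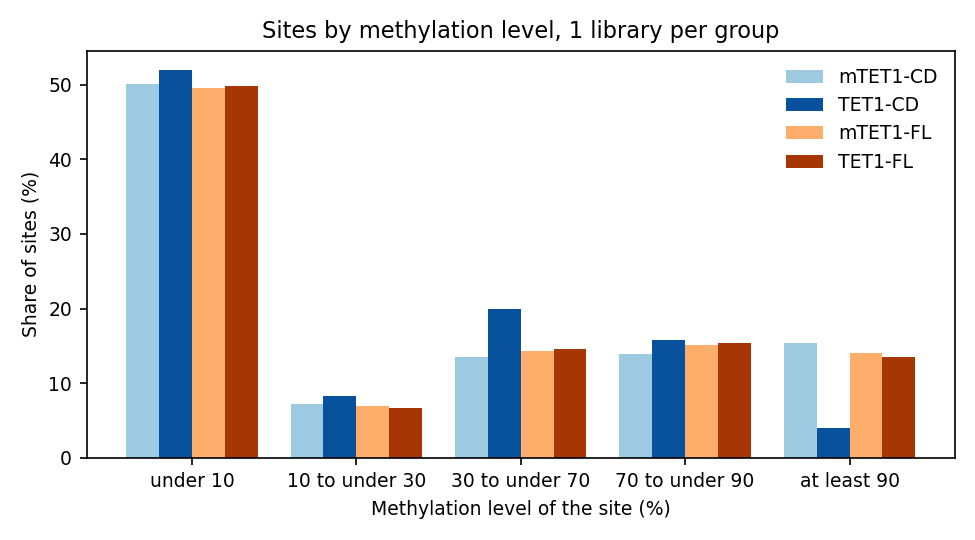
Share of the 30593 common sites (y axis, %) in 5 methylation classes (x axis, %) for the 4 libraries, 1 bar per library. TET1-CD has 4.02% of its sites in the top class, whereas the other libraries have between 13.6% and 15.3%.

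The first contrast asked what the unmutated catalytic-domain construct did to methylation relative to its m form, both on day 3. Methylation was lower in TET1-CD at most methylated sites. Of 8919 sites that were at least 70% methylated in mTET1-FL, 94.7% had a lower level in TET1-CD than in mTET1-CD, and their median change was -12.0 points (95% interval -12.3 to -11.8). Over all sites the mean change was -5.93 points (counting interval -5.97 to -5.89). The mean difference between mTET1-FL and mTET1-CD was -0.071 points (counting interval -0.10 to -0.040). Without sites called between them it was 0.030 points. Weighted by reads it was 8.26 points, larger in size than the weighted TET1-CD change of -6.01 points and of the other sign. Each library was weighted by its own reads, so the weighted values also depend on how its depth was spread over sites. Among 3947 sites of at least 90% in both m libraries, 28.1% stayed at 90% or above in TET1-CD, against 92.1% in TET1-FL.

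Single-site calls went the same way. Fisher's exact test called 2690 sites lowered in TET1-CD and 27 raised. The lowered sites lay in 1449 different windows of 100 kb. Their median level was 83.7% in mTET1-CD and 54.3% in TET1-CD. Of the 1999 lowered sites that began at 70% or more, 1 fell below 10%. Without the size threshold, 8451 sites were lower and 114 higher at an adjusted p below 0.05. Between the m libraries the same test called 265 sites, 161 of them lower and 104 higher in mTET1-FL. The spread between libraries exceeded binomial sampling. With the variance multiplied by 5.77, the dispersion between the m libraries, a z test in place of Fisher's test called 988 lowered and 1 raised sites.

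The 10 named sites with the largest falls had levels from 86.1% to 97.6% in mTET1-CD, and each was also called with the inflated variance. With reads thinned to 20, only those on chromosomes 10 and 17 were still called. On chromosome 17 at position 18226423, methylation was 93.7% in mTET1-CD (Wilson 95% interval 91.2 to 95.6, 477 reads) and 19.8% in TET1-CD (12.7 to 29.4, 86 reads; Fisher's exact test, adjusted p = 2.22e-45). The covered site next to it, 226 bp away, changed by -4.67 points. On chromosome 4 at position 30333791 methylation was 93.5% in mTET1-CD (398 reads) and 31.2% in TET1-CD (269 reads), and the neighbour 154 bp away changed by -49.6 points. On chromosome 10 at position 118917272 it was 96.0% and 40.1%, with a change of -55.6 points at its neighbour 98 bp away. On the same chromosome at position 76825505 it was 97.3% (995 reads) and 42.4% (399 reads), and each of the 3 covered sites within 1000 bp was also called lowered. The levels were 86.1% and 22.8% on chromosome 22 at position 23962572, a site with no covered neighbour within 1000 bp. They were 97.6% and 35.9% on chromosome 2 at position 31213830, and on chromosome 17 at position 8867567 a level of 89.3% in mTET1-CD fell by 58.3 points. On chromosome 18 at position 75260488 the levels were 92.3% and 35.2%. On chromosome 22 they were 88.9% and 33.9% at position 43271708 and 95.04% and 40.5% at position 48708811. The 1 covered neighbour of the former changed by -13.8 points and the 3 of the latter by a median of -1.57, and none of these was called. In TET1-FL these 10 sites had levels between 73.6% and 98.1%. Against mTET1-FL, position 43271708 changed by -7.88 points and position 30333791 by -2.61, below the size threshold (Fisher's exact test, adjusted p = 2.65e-09 and 0.0461). The rest did not reach an adjusted p below 0.05, including position 75260488 with -12.6 points.

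Of the 5 named raised sites, 3 had low methylation in both FL libraries, and 1 of the 5, on chromosome 19, was also called with the inflated variance. On chromosome 16 at position 730533 methylation was 8.45% in mTET1-CD (142 reads) and 49.3% in TET1-CD (69 reads). There it was 0 of 873 reads in mTET1-FL, which allows a share of up to 0.344%, and 0 of 816 reads in TET1-FL, which allows up to 0.368%. The level rose from 39.4% to 70.1% on chromosome 5 at position 65927802, where mTET1-FL had 0.84%. It rose from 24.2% to 53.5% on chromosome 19 at position 1430012, where mTET1-FL had 3.03%. It rose from 21.7% to 50.5% on chromosome 10 at position 6528806, and from 32.5% to 59.2% on chromosome 11 at position 593283, where mTET1-FL had 55.5% and 72.7%. The sites on chromosomes 5, 10, 11 and 19 also differed between the m libraries by the same test. At those on chromosomes 10 and 11, mTET1-CD was the lowest of the 4 libraries, with 55.7% and 73.7% in TET1-FL. On chromosomes 5, 16 and 19 both FL libraries were lower than mTET1-CD. No covered site within 1000 bp of the 5 was called raised. With 27 raised among 30593 sites, none was likely there in any case. Of the 27 raised sites, 15 also differed between the m libraries, against 52 of the 2690 lowered ones and 265 of all 30593 sites. Both tests used the mTET1-CD library, so an outlying level in it alone could give both calls. When sites called between the m libraries were left out, 2637 lowered and 12 raised sites were called in TET1-CD.

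The second contrast asked the same of the full-length construct on day 7. Methylation in TET1-FL stayed close to that in mTET1-FL. The median change of 8941 sites that were at least 70% methylated in mTET1-CD was -0.20 points (95% interval -0.25 to -0.16), and 54.8% of them were lower. The mean change over all sites was -0.24 points (counting interval -0.27 to -0.21). Weighting the sites of each library by its own reads, which mixes depth with methylation, turned the sign of this mean to 2.25 points. The 2 m libraries then differed by 8.26 points. Fisher's exact test called 8 sites lowered and 3 raised, and 287 lower and 101 higher sites without the size threshold. Between the m libraries 265 sites were called. No site was called with the inflated variance. In Fisher's test 2492 of the 30593 sites had an unadjusted p below 0.05, which a share of up to 0.05 of unchanged sites would reach by read sampling alone. Spread between libraries beyond read sampling adds to that share. The inflated variance used a z test with the factor of 5.77 from the m libraries, whereas the dispersion within the FL pair was 2.31. It is thus a strict check for this contrast.

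Of the called TET1-FL sites, 5 lowered and 1 raised site had 50 reads or more in each library. On chromosome 20 at position 29527090 methylation was 56.4% in mTET1-FL (Wilson interval 47.9 to 64.5, 133 reads) and 29.5% in TET1-FL (19.6 to 41.9, 61 reads), with an adjusted p of 0.0492 by Fisher's exact test. This call was lost with at least 10 reads and on autosomes only. The site also differed between the m libraries, a comparison that shares the mTET1-FL library with this contrast. The levels were 40.5% and 15.2% on chromosome 1 at position 2714870, and 41.7% and 18.8% at position 107915074 of the same chromosome. They were 91.5% and 68.2% on chromosome 7 at position 4790955, and 90.9% and 70.2% on chromosome 21 at position 46426975. The sites on chromosomes 7 and 21 were also lowered in TET1-CD, with changes of -26.4 and -23.0 points. The raised site, on chromosome 1 at position 29048377, had 47.4% in mTET1-FL and 74.0% in TET1-FL. No covered site within 1000 bp of these 6 was called in the same direction in TET1-FL, and the site at position 107915074 had no covered neighbour in that range. With 8 lowered and 3 raised among 30593 sites, none was likely there in any case.

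The test of the difference between the contrasts found a lower change in TET1-CD than in TET1-FL at 2385 sites and a higher change in TET1-CD at 32 (z test with Benjamini-Hochberg adjustment). The 32 became 17 without sites called between the m libraries, 4 with at least 100 reads and 0 with reads thinned to 20. Of the 2690 sites lowered in TET1-CD, 78.8% were among the 2385. The mean difference of the changes was -5.69 points. With the inflated variance 446 and 1 sites were past the thresholds. The 10 largest differences all had the lower change in TET1-CD and included 7 of the sites named above. The other 3 lay on chromosome 20 at position 60918404, on chromosome 13 at position 49599910 and on chromosome 12 at position 121254912, with changes in TET1-CD of -49.9, -52.2 and -47.9 points; with the inflated variance the difference was lost at the first and last of these and at position 23962572 of chromosome 22. The contrasts differ in both construct form and sorting day. Among 8484 sites of at least 70% in both m libraries, 1886 were lowered in TET1-CD and 3 in TET1-FL. Of these, 2 were lowered in both contrasts, where 0.667 would be shared by independent lists (Fisher's exact test, p = 0.126). With 3 sites in the TET1-FL list the test has little power.

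The change was then set against the level a site had at baseline. In TET1-CD the median change was -0.09 points at sites below 10% (-0.012 to -0.18 with other read minimums), -4.34 at 10 to under 30%, -10.0 at 30 to under 70%, -13.4 at 70 to under 90% and -10.8 at 90% or more. The share of sites called lowered was 0.12%, 0.85%, 14.9%, 26.4% and 18.1% in these classes. Sites below 20% in mTET1-CD could not fall by the 20 points a call needs. The mean level there was 1.14% in the first class and 18.6% in the second. Relative to the level in mTET1-CD, the mean fell by 33.9% in the lowest class, where it was 1.14%, and fell by 13.3% in the highest. In TET1-FL these relative changes were -11.3% and -0.46%. At sites below 1% in both FL libraries the pooled level itself was 0.474% in mTET1-CD and 0.239% in TET1-CD. In TET1-FL the class medians lay between -0.24 and 0.12 points, and that at 30 to under 70% was 0.34 with at least 100 reads.

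**Figure D2:**
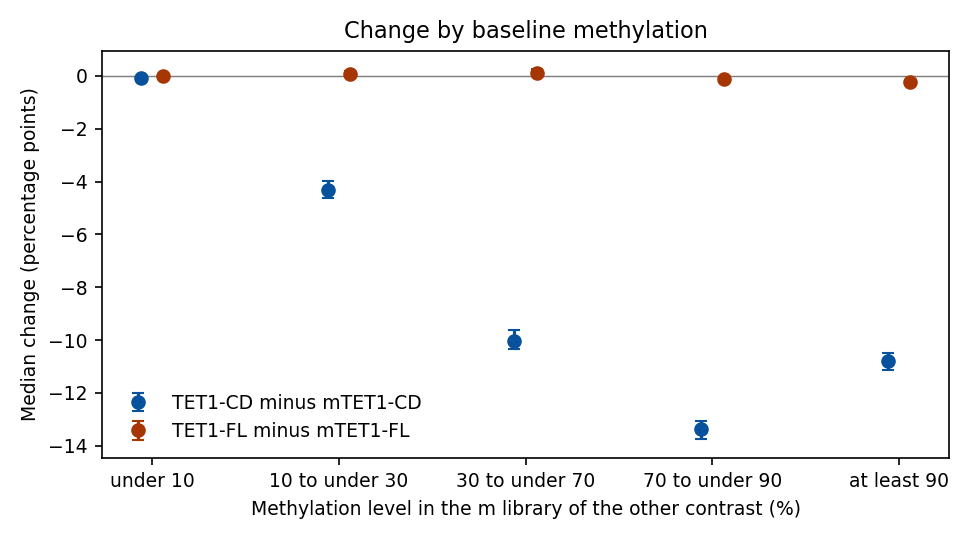
Median change in methylation (y axis, percentage points) by the level of the site in the m library of the other contrast (x axis, %), for both contrasts. Bars are 95% order-statistic intervals of the median, not the spread of single sites. The TET1-CD median is -13.4 points at 70 to under 90%, and the TET1-FL medians lie between -0.24 and 0.12 points.

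Because the series title speaks of methylation spreading, sites were also compared by their surroundings. In TET1-CD the median change of methylated sites was lower next to an unmethylated site than next to a methylated one. At 70 to under 90% the median change was -18.4 points (95% interval -24.8 to -13.6, 75 sites) where the nearest covered site within 1000 bp was below 10%, and -12.8 points (-13.3 to -12.3, 2716 sites) where it was at least 70%. At 90% or more the medians were -21.6 (-35.8 to -12.4, 31 sites) and -10.8 points (-11.1 to -10.4, 3211 sites). At 30 to under 70% they were -12.9 and -10.0 points, and at 10 to under 30% they were -4.76 and -4.43 points with overlapping intervals. Pooled over all sites of 10% or more the order was the opposite, -7.48 against -10.9 points, and the sites had mean levels of 29.8% and 80.4% in mTET1-CD. In TET1-FL the same split gave medians of -1.63 against 0.23 points at 30 to under 70%, -1.72 against -0.10 at 70 to under 90%, and -1.36 against -0.23 at 90% or more (20 and 3661 sites). Matched in 10-point classes, the difference between neighbour classes was -3.23 points in TET1-CD (bootstrap 95% interval -4.12 to -2.36) and -0.99 in TET1-FL (-1.38 to -0.66). With classes taken from TET1-CD itself the TET1-CD value was -0.98 points (-2.53 to 0.64), and over all class choices the TET1-FL value ran from -1.92 to -0.57. In the main comparison the classes of each contrast came from the m library of the other, and within the class of 70 to under 90% the mean in mTET1-CD was still 71.5% beside unmethylated and 83.4% beside methylated sites. The same measure for mTET1-FL minus mTET1-CD, with classes from TET1-FL, was larger in size, 7.68 points (7.05 to 8.31). Its sign is opposite in this order of subtraction and would turn in the reverse order.

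**Figure D3:**
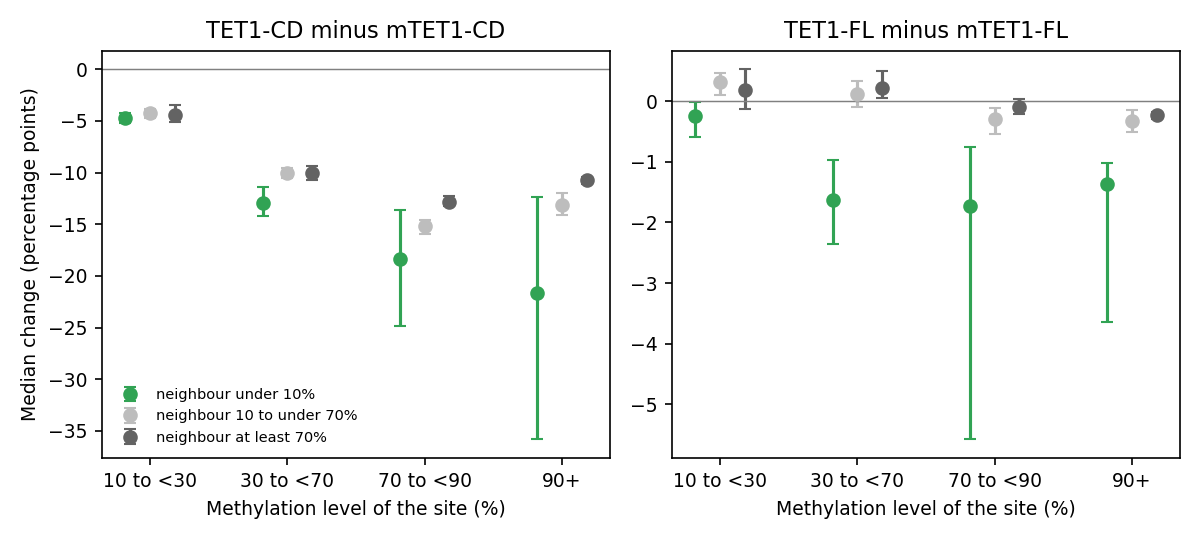
Median change (y axis, percentage points, scales differ between panels) by the level of the site (x axis, %) and of its nearest covered site within 1000 bp (colours), for TET1-CD and TET1-FL. Bars are 95% order-statistic intervals of the median, not the spread of single sites. At 70 to under 90% the TET1-CD medians are -18.4 beside an unmethylated and -12.8 beside a methylated neighbour.

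The change was also set against the local number of CCCGGG sites. Among sites of at least 70%, the TET1-CD median was -13.8 points with no other site within 500 bp (85 sites; -9.16 with at least 10 reads), -12.0 with 1, -12.4 with 2 to 3 and -10.5 with 4 or more (95% interval -11.5 to -9.49, 938 sites). In TET1-FL the medians were 0.13, -0.12, -0.27 and -0.42 points. The gap in TET1-CD between 4 or more and 1 other site was 1.54 points, against 0.12 with a window of 1000 bp, 0.52 with a window of 250 bp and 2.39 at sites of at least 90%.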

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

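The tests in this part of a fixed lost fraction and of a single-library feature were chosen after the result was seen. The sites below stood out because the 2 contrasts differed there by a test of the difference itself. The counts were 2385 sites with a lower change in TET1-CD than in TET1-FL and 32 with a higher one. Among the named sites, the difference of changes (TET1-CD minus TET1-FL) on chromosome 17 was -72.4 points at position 18226423 and -56.2 at position 8867567. On chromosome 22 it was -60.8 points at position 23962572, -47.1 at position 43271708 and -50.9 at position 48708811. On chromosome 10 it was -53.3 points at position 118917272 and -54.9 at position 76825505. It was -59.6 points on chromosome 4 at position 30333791, -57.4 on chromosome 2 at position 31213830 and -44.5 on chromosome 18 at position 75260488. It was -62.4 points on chromosome 20 at position 60918404, -57.0 on chromosome 13 at position 49599910 and -53.4 on chromosome 12 at position 121254912. Higher changes in TET1-CD were 40.8 points on chromosome 16 at position 730533, 31.6 on chromosome 5 at position 65927802, 29.9 on chromosome 19 at position 1430012, 28.6 on chromosome 10 at position 6528806 and 25.7 on chromosome 11 at position 593283. On chromosome 1 at position 107915074 the difference was 43.2 points, from a rise in TET1-CD and a fall in TET1-FL at a site whose nearest covered neighbour lies 429698 bp away.

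A loss of a fixed fraction of methylated reads would multiply the odds of methylation by the same factor at every level. The median log2 change of the odds in TET1-CD was -1.12 at 70 to under 90% and -2.04 at 90% or more, a difference of 0.93 (bootstrap interval 0.87 to 0.99), which argues against such a loss as the whole cause of the broad fall. A change in which sites were sampled could not by itself produce the fall, since each change was taken within a site over 1 common set. A split by relative depth therefore does not test it. Methylated sites in the middle one of 5 equal groups of relative depth changed by a median of -11.5 points (-11.9 to -11.0). The median was -13.5 points (-14.2 to -13.0) in the group of lowest depth relative to mTET1-CD and -11.6 in the highest. A feature of the single TET1-CD library stays open, because no second TET1-CD library was analysed here. The mean difference between the m libraries was -0.071 points with each site counted once. Weighted by each library's own reads it was 8.26 points, where TET1-CD changed by -6.01. These weighted values also carry differences in depth between the libraries. An action of the unmutated catalytic-domain construct is the biological explanation the design offers, and it may account for the fall, but with 1 library per construct it remains a hypothesis.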

How the results depend on the processing

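The settings with the TET1-CD counts as deposited and without sites called between the m libraries were chosen after seeing the data. The mean fall in TET1-CD kept its direction under each setting that recomputed it, and the mean changes of TET1-FL and between the m libraries did not. Means and gaps that left their interval, and counts that moved by over 1.5 times, are given by setting. With at least 10 reads, the mean was 34.9% in mTET1-CD and 29.0% in TET1-CD, and the mean change was -5.85 points for TET1-CD and -0.13 for mTET1-FL minus mTET1-CD. With at least 50 reads the means were 34.9% in mTET1-CD, 34.8% in mTET1-FL and 34.7% in TET1-FL, with changes of -6.00 and -0.16 for TET1-CD and TET1-FL; 9 sites were raised in TET1-CD, 5 lowered and 1 raised in TET1-FL, and 134 differed between the m libraries. With at least 100 reads the means were 34.4% (mTET1-CD), 28.4% (TET1-CD), 34.4% (mTET1-FL) and 34.3% (TET1-FL), and the changes of TET1-FL and between the m libraries were -0.082 and -0.031. That minimum left 1648 lowered and 2 raised sites in TET1-CD, 0 and 0 in TET1-FL, 66 between the m libraries, 1556 with a lower change in TET1-CD and 0 shared lowered sites, with fewer sites tested. With sites covered in the 2 libraries compared, the means were 34.3% (mTET1-CD), 28.5% (TET1-CD), 40.4% (mTET1-FL) and 40.2% (TET1-FL), the changes -5.79, -0.18 and -0.17 (m libraries), and 5 sites were raised in TET1-FL. Weighted by coverage, the means were 29.3%, 23.3%, 37.6% and 39.8% in the same order and the changes -6.01, 2.25 and 8.26. The sign turned for TET1-FL and the m libraries. Each library was weighted by its own reads, so these values mix the spread of depth over sites with methylation. Thinned to 20 reads, the means were 34.8% (mTET1-CD), 28.9% (TET1-CD) and 34.7% (mTET1-FL), and the changes -5.86 for TET1-CD and -0.013 between the m libraries. Thinning left 33 sites lowered and 0 raised in TET1-CD, 0 and 0 in TET1-FL, 19 between the m libraries and 19 with a lower change in TET1-CD, so depth limits the single-site calls. On autosomes only, the means were 34.9% (mTET1-CD), 28.9% (TET1-CD) and 34.8% (mTET1-FL), and the m libraries differed by -0.11. With a size threshold of 10 points the calls were 6558 lowered and 66 raised in TET1-CD, 30 and 15 in TET1-FL, 969 between the m libraries and 5736 with a lower change in TET1-CD. At 30 points they were 771 and 12, 2 and 1, 123 and 662. With the inflated variance they were 988 and 1, 0 and 0, 73 and 446. With classes from the same m library the gap between the highest and lowest baseline class was -11.2 points in TET1-CD and -0.32 in TET1-FL. A density window of 1000 bp gave a gap of 0.12 points between 4 or more and 1 other site in TET1-CD. At a baseline of at least 70%, the gap between neighbour classes was -9.04 points in TET1-CD, opposite in sign to the pooled 3.46, and -1.36 in TET1-FL. The TET1-CD counts as deposited gave means of 35.0%, 29.0%, 34.9% and 34.6% (mTET1-CD, TET1-CD, mTET1-FL, TET1-FL) and 45 raised sites in TET1-CD. Without sites called between the m libraries the means were 34.6% (mTET1-CD), 28.7% (TET1-CD) and 34.7% (mTET1-FL), the m libraries differed by 0.030, and 12 sites were raised in TET1-CD. The count of sites with a higher change in TET1-CD than in TET1-FL, 32 in the report, was 15 with at least 50 reads, 4 with at least 100, 0 after thinning, 55 and 17 at 10 and 30 points, 1 with the inflated variance, 49 with the counts as deposited and 17 without sites called between the m libraries. Counting these and the class medians, 35 values moved and 133 did not. Among the main means, changes, gaps and counts, 89 values moved and 82 did not. Of the calls at named sites, 25 were lost by thinning, 13 by the inflated variance, 9 at 30 points, 1 with at least 10 reads and 1 on autosomes only; only thinning could change the levels at single sites, so the other settings do not test their direction. Of the 31 named calls, 17 were not assessed with at least 100 reads and 5 not without sites called between the m libraries, because their sites left the set. The alternatives for gene lists were not run, because no site was assigned to a gene.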

Other observations

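The tests in this part of shared fragments, of baseline level beside unmethylated sites, of neighbour differences between any 2 libraries in TET1-CD, and of regional differences were chosen after the result was seen. The fall in TET1-CD varied along the genome. Among methylated sites (at least 70% in mTET1-FL), the median change by chromosome ran from -7.34 points on chromosome 6 (95% interval -9.06 to -6.34, 281 sites) to -14.6 points on chromosome 16 (-15.6 to -13.9, 574 sites). Chromosome 19 had -14.1 points (836 sites), chromosome 20 had -13.6 and chromosome 17 had -13.5, while chromosome 13 had -8.72, chromosome 5 had -9.33 and chromosome X had -12.2 (-15.1 to -9.47, 114 sites). In TET1-FL the chromosome medians lay between -0.57 points on chromosome 19 and 0.39 on chromosome 18. They were -0.34, -0.45 and -0.40 on chromosomes 16, 20 and 17, and 0.05, 0, -0.03 and -0.07 on chromosomes 6, 13, 5 and X. Among these chromosomes, those with larger falls in TET1-CD tended to have lower medians in TET1-FL.

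Nearby methylated sites changed together in TET1-CD. Across pairs of sites (at least 70% as the mean of the m libraries) the correlation of changes was 0.58 at 100 to under 300 bp, 0.24 at 1000 to under 5000 bp, 0.10 at 10000 to under 30000 bp and 0.04 at 30000 to under 100000 bp; sites are not independent replicates. The size-selected fragments were shorter than 1000 bp, per the labels' protocols, so the value of 0.238 (0.225 to 0.255 with any 1 chromosome left out, 1736 pairs) argues against reads of shared fragments as the whole source. After the median change of sites with a like baseline was taken off, the correlation was 0.228 (0.215 to 0.240), which argues against a shared baseline level. At that distance the correlation was 0.0401 in TET1-FL against mTET1-FL and 0.0229 between the m libraries. These values argue against regional differences as strong as in TET1-CD between any 2 libraries, although the m libraries reached 0.20 at 100 to under 300 bp. A weaker regional pattern shared with TET1-FL stays open. Changes there were small, with a standard deviation over sites of 3.33 points against 9.36 in TET1-CD, and counting error lowers a correlation. A hypothesis is that susceptibility to the catalytic-domain construct may vary by region, with a feature of the single TET1-CD library still open.

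The larger fall beside unmethylated sites was weighed in both contrasts. The differences matched on the other contrast's m library were -3.23 points in TET1-CD and -0.991 in TET1-FL, but that matching left the levels in the library of the change unequal; over classes from each library or the mean of the m libraries, they ran from -4.80 to -0.98 (with classes from TET1-CD, an interval that includes 0) and from -1.92 to -0.57. With reads of the same m library split 50 times into a part for the classes and a part for the change, the median was -3.58 points in TET1-CD (-4.46 to -2.87 over splits) and -1.71 in TET1-FL (-2.06 to -1.43), which argues against baseline level as the whole cause, although the levels left over were still lower beside unmethylated sites, by a median of -2.69 and -1.59 points. A difference of that size between libraries stays open for both, since the matched difference between the m libraries was 7.68 points with classes taken from TET1-FL and 6.02 with classes from TET1-CD. The sign of that difference is opposite only in the order of subtraction used, mTET1-FL minus mTET1-CD. It comes from 1 pair that differs in construct and day, so only its size can be compared. An effect at the edges of unmethylated regions may exist in either contrast, but these libraries alone do not set it apart from such differences.

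At 13075 sites below 1% in both FL libraries, the pooled methylation was 0.474% in mTET1-CD (Wilson interval 0.469 to 0.480) and 0.239% in TET1-CD (0.234 to 0.244). At 11267 sites below 1% in both CD libraries it was 0.0945% in mTET1-FL and 0.0713% in TET1-FL. Of the 27 sites raised in TET1-CD, 7 were below 10% in both FL libraries, and 5 of these had at least 10% in mTET1-CD.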
